A study of Arabidopsis thaliana with 6 samples.

How the data were processed

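RNA was measured in whole 1-day-old Arabidopsis seedlings of the wild type Col-0 and the mutant line vil1-1, with 3 libraries of each. Per the labels, seeds were stratified for 3 days at 4 °C in the dark and seedlings were grown at 22 °C with 16 h light and 8 h dark. The series design describes the 3 libraries of a genotype as biological replicates. Groups and replicate numbers were taken from the sample titles.

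Bowtie2, featureCounts and edgeR, and the TAIR10 build, are named in the submitters' processing notes, which give no versions and no order of steps. The deposited count files hold whole-number counts per gene, 1 file per library, with 33602 rows each and no normalization. Library kit, strand setting and treatment of multi-mapping reads are not given in the sources used here. Reads of overlapping genes, of antisense partners and of near-identical copies can therefore not be told apart. Chloroplast and mitochondrial loci held 0 counts in every library.

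The authors' deposited table lists 25005 genes with a log2 fold change of vil1-1 over Col-0, a mean log2 CPM, an F score and a p-value. How the authors made it beyond the tools above is not given in the sources used here, nor is the number of libraries behind it. For the 24290 genes with an F under 20, its p-values differed from a chi-square test on 1 degree of freedom by at most 0.002 in log10. It holds no adjusted p-values. Benjamini-Hochberg adjustment over its 25005 genes was added here, so adjusted p-values quoted from it are computed from the authors' p-values. Its log2 fold changes and CPM are the authors' and are given without SD or n.

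Library totals were 48868, 66546 and 64554 counts in Col-0 replicates 1, 2 and 3, and 46917, 49341 and 63303 in vil1-1 replicates 1, 2 and 3. A single count was worth 15 to 21.3 CPM, and 3 counts, the most that a count of 0 allows, 45.1 to 63.9 CPM. Binomial intervals and floors cover counting error only. Bootstrap intervals resample genes, not libraries. Intervals of EPR1 and of the seed coat markers use standard errors from the log2 fold changes and F scores of the authors' deposited table. At this depth most genes could not be tested singly: edgeR's default filter on low counts kept 942.

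The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the deposited counts of all 6 libraries, with TMM normalization, genotype as the only term and Benjamini-Hochberg adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are a library's counts scaled to a total of 1000000, without TMM factors. The same code was tested on 5 simulated data sets for this comparison, each with 200 of the tested genes changed and 935 genes tested on average. It recovered 77.3% of genes changed 2-fold and 100% of genes changed 4-fold, and 5.1% of its calls were false. Every simulated gene had the same dispersion, 0.00983, so differences between genes and outlying single libraries were not simulated. These rates may therefore be too favourable for the real counts.

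Before the data were examined, 24 gene lists, the tests and the rule for named genes were fixed. A further list, ribosomal proteins by product name, was taken by a fixed wording from the reference annotation. It was planned as cytosolic ribosomal proteins, but its 290 genes include some nuclear genes of organelle ribosomes. The rule named VIL1, the other VIN3-like genes, ABI3, ABI4, ABI5, FLC, CLF, SWN, EMF2 and VRN2. It added the 8 largest and 8 smallest log2 fold changes among called genes with a mean of at least 5 CPM in the higher group and separate CPM ranges. It also added up to 4 called members per list, or up to 2 members with the highest CPM where none was called. For the authors' deposited table the rule was applied without the condition on ranges. Other genes named were chosen after their values were seen.

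The planned list test was limma's camera (limma 3.58.1) with a preset correlation of 0.01 on log2 CPM with a prior count of 2. It needs at least 3 tested members, which only 4 lists had. List tests added after seeing the data were an edgeR fit in which each list's counts were summed per library, which gave a test for 17 lists, and limma's cameraPR on the signed root of F in the authors' deposited table, for all 25 lists. Adjusted p-values of list tests are Benjamini-Hochberg values over the lists tested. Summed counts lead with the most abundant members, so each called sum was run again without the member whose CPM rose most, also after seeing the data. A correlation between genes cannot be estimated from that table, so cameraPR used the preset value and its p-values may be too small for lists whose genes vary together.

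Other settings fixed before the data were examined were DESeq2 1.42.0, RLE normalization, library totals without TMM, limma-voom, no filter, a filter of CPM above 1 in at least 3 libraries, the replicate number as a block, organelle loci left out, thinning to 46917 counts per library, each library left out in turn, an adjusted p under 0.01, a minimum absolute log2 fold change of 1, camera with an estimated correlation, and fry. Settings added after seeing the data left out Col-0 replicates 2 and 3 together or the 4 ribosomal RNA loci, or limited the authors' deposited table to genes with a mean log2 CPM of at least 1, or ran cameraPR on ranks.

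Gene symbols, products and coordinates came from the RefSeq annotation of TAIR10.1, to which 32835 of the 33602 loci matched. The count files give no coordinates, and the build named by the submitters is TAIR10, so coordinates are those of TAIR10.1. Other tests were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.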

Results

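Transcript levels were compared between 3 libraries of wild-type Col-0 and 3 libraries of vil1-1, a line mutated in VIL1, from whole 1-day-old seedlings. The comparison asked which genes differ between the genotypes just after germination. VIL1 encodes a PHD finger protein of the VIN3-like family, which works with Polycomb repressive complex 2. The libraries held 46917 to 66546 gene counts, with 7799 to 9015 genes detected in each, so the counts resolved only the more abundant transcripts. The authors' deposited table lists 25005 genes, of which 10137 had no count in any of the 6 count files.

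VIL1 (AT3G24440, chromosome 3, 8875784 to 8878481, minus strand, TAIR10.1) had 0 counts in all 6 libraries. A count of 0 allows up to 45.1 to 63.9 CPM per library, so the counts could not check the genotype labels. The authors' deposited table gives VIL1 at 14.2 CPM with a log2 fold change of -0.91 (adjusted p = 0.000309), lower in vil1-1. At that level 4.82 VIL1 counts would be expected over the 6 libraries (Poisson p = 0.008 for 0 counts), or 2.68 (Poisson p = 0.069) after scaling to the median ratio of counts to the authors' deposited table. Both p-values take counts to follow that level with counting error alone. Of the genes above 300 CPM there, 69.4% lay outside the 99% Poisson range, so neither p-value shows whether 0 counts is unusual. VIN3, the family member that vernalization induces, was higher in vil1-1 in the authors' deposited table, with a log2 fold change of 1.81 at 2.43 CPM (adjusted p = 0.0313). VIN3 had 0, 0 and 1 counts in Col-0 and 4, 0 and 1 in vil1-1. VEL1 had a log2 fold change of 0.07 (adjusted p = 0.764) in the authors' deposited table, where VEL2 and VEL3 were under 1 CPM and did not pass the test. VEL1 had 0, 1 and 2 counts in Col-0 and 3, 3 and 9 in vil1-1, and the 5 genes together 4 and 20, too few for a test. As a list, the 5 VIN3-like genes were not called (adjusted p = 0.636, cameraPR).

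Genes of the seed's late embryogenesis abundant (LEA) programme, whose proteins protect dry embryos, were higher in vil1-1. LEA4-5 (AT5G06760, chromosome 5, 2089445 to 2090430) stood at 27.2 ± 5.8 CPM in Col-0 and 251.4 ± 47.1 CPM in vil1-1 (SD, n = 3 each), a log2 fold change of 3.10 (SE 0.55, edgeR adjusted p = 5.79e-05). The dehydrin XERO1 rose by 1.76 (SE 0.39, edgeR adjusted p = 0.00248). Both LEA genes with enough counts for a test were called, over all genes and adjusted over the list alone. Their Col-0 counts were low, with 1, 2 and 2 for LEA4-5 and 7, 5 and 6 for XERO1. Both passed the filter through their vil1-1 counts, so the share of tested members called is no evidence for the list. Summed over the list's 19 genes, counts were 336.9 ± 57.5 CPM in Col-0 and 1437.3 ± 459.8 CPM in vil1-1 (SD, n = 3 each), a log2 fold change of 2.13 (SE 0.24, edgeR adjusted p = 2e-11). Without XERO1, the member with the largest rise in CPM, the sum rose by 2.25 (SE 0.26, edgeR adjusted p = 6.23e-11). Of the 19 genes, 16 were higher and none lower in the authors' deposited table, with a median log2 fold change of 2.12 (adjusted p = 1.99e-192 in cameraPR, and 9.87e-09 on ranks). LEA7 (2.23), LEA76 (2.32) and LEA18 (2.12) were among the members with the smallest p in the authors' deposited table.

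Seed storage and oil body genes summed to 182.5 ± 105.7 CPM in Col-0 and 457.7 ± 55.1 CPM in vil1-1 (SD, n = 3 each), a log2 fold change of 1.44 (SE 0.33, edgeR adjusted p = 0.000281). PER1, a seed peroxiredoxin, made up 65% of this rise, and the other 17 genes, at 121.2 ± 66.1 CPM in Col-0 and 217.6 ± 122 CPM in vil1-1 (SD, n = 3 each), had too few counts for a test. Of the 18 genes in the authors' deposited table, 10 were higher and none lower (adjusted p = 4e-17 in cameraPR, and 3.1e-07 on ranks). They include PER1 at 1.91, the oleosin gene OLEO5 at 1.83 and the cruciferin gene CRA1 at 0.98. No member had enough counts to be tested singly.

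As a list, cell wall loosening genes, expansins among them, rose in vil1-1. The listed gene CP1 did not, with 0.14 in the counts (edgeR adjusted p = 0.834) and -0.02 in the authors' deposited table. EXPA2 stood at 237.2 ± 76 CPM in Col-0 and 637.3 ± 43 CPM in vil1-1 (SD, n = 3 each), a log2 fold change of 1.41 (SE 0.27, edgeR adjusted p = 0.000183), and EXPA10 rose by 1.00 (SE 0.26, edgeR adjusted p = 0.0114). These 2 of the 5 tested members were called, over all genes and adjusted over the list alone. The list's summed counts rose by 0.64 (SE 0.14, edgeR adjusted p = 0.000281), from 1946.8 ± 228.7 to 2926.7 ± 190.4 CPM (SD, n = 3 each), and by 0.48 without EXPA2 (SE 0.16, edgeR adjusted p = 0.014). Camera called the list higher (adjusted p = 0.000589), a call lost at adjusted p = 0.071 with an estimated correlation. Of its 8 genes, 6 were higher in the authors' deposited table, or 7 adjusted over the list alone, with a median of 1.00 (adjusted p = 2.32e-36 in cameraPR, and 0.000243 on ranks).

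Among storage lipid mobilisation genes, which turn seed oil into sugar, the rise in the counts was that of ICL. ICL, the isocitrate lyase of the glyoxylate cycle, went from 5744.7 ± 443.4 to 8515.4 ± 751 CPM (SD, n = 3 each), a log2 fold change of 0.60 (SE 0.12, edgeR adjusted p = 0.000358), and was the 1 called gene of the 8 tested, also adjusted over the list alone. Summed counts of the 15 genes rose by 0.33 (SE 0.09, edgeR adjusted p = 0.00251), a call lost with no filter (edgeR adjusted p = 0.118) and with CPM above 1 (edgeR adjusted p = 0.113). ICL made up 99.1% of this rise, and the sum of the other 14 genes did not differ (log2 fold change 0.05, SE 0.10, edgeR adjusted p = 0.738). Camera did not call the list (adjusted p = 0.384, and adjusted p = 0.466 with an estimated correlation). Of the 15 genes, 7 were higher and ACX1 lower, at -0.50, in the authors' deposited table (list adjusted p = 0.00186, cameraPR).

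**Figure D1:**
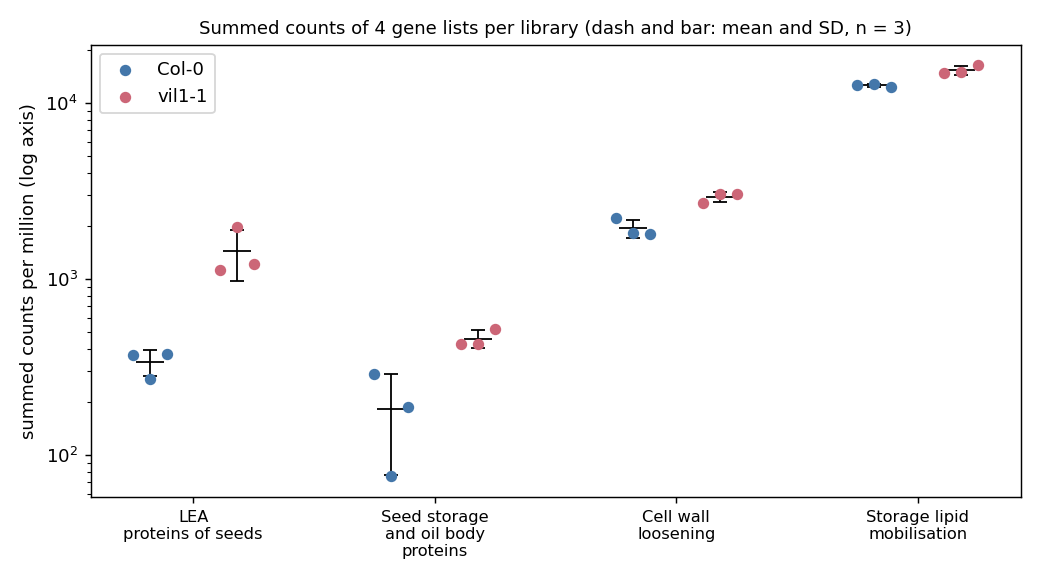
Summed CPM (log axis) of 4 gene lists in each library of Col-0 and vil1-1, with dashes and bars for the mean and SD of 3 libraries. LEA counts averaged 336.9 CPM in Col-0 and 1437.3 CPM in vil1-1, and storage lipid mobilisation 12652.5 and 15449 CPM.

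Across all 942 genes tested, edgeR called 35, with 26 higher and 9 lower in vil1-1. At an absolute log2 fold change of at least 1, 19 were higher and 6 lower. After LEA4-5, the largest rises were of AT1G04560, an AWPM-19-like gene, at 2.50 (SE 0.38), and of the retroelement-derived locus SADHU3-2 at 2.19 (SE 0.47). FAD3, the endoplasmic reticulum desaturase that makes linolenic acid, rose by 1.77, AT4G33560, of a wound-responsive family, by 1.67, the aldolase gene FBA6 by 1.64 and the glycosyl hydrolase gene AT5G20950 by 1.63. Rises in the authors' deposited table were much smaller for FAD3 (0.82), FBA6 (0.56) and AT5G20950 (0.29). They were close to those from the counts for AT1G04560 (2.37), SADHU3-2 (2.035) and AT4G33560 (1.65). All of these genes were picked for the largest rises in the counts and passed the filter through their vil1-1 counts. Col-0 counts were 4, 8 and 4 for FAD3, 2, 8 and 3 for FBA6, and 3, 6 and 3 for AT5G20950. Smaller rises in the authors' deposited table can therefore not be read as a difference between the 2 sources. From the counts, AT5G08200 had a log2 fold change of 1.27 (SE 0.38), with 46 counts in vil1-1 replicate 1 and 11 and 14 in the other vil1-1 libraries. Without vil1-1 replicate 1 its log2 fold change was 0.23 (SE 0.43, edgeR adjusted p = 0.87). The call of AT5G08200 was also lost without Col-0 replicate 2 (1.17, edgeR adjusted p = 0.116) and without Col-0 replicate 3 (1.12, edgeR adjusted p = 0.0688), and stayed in the other 3 settings with 1 library left out.

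Lower in vil1-1 were LDA, the limit dextrinase that debranches starch, at -1.53 (SE 0.35), and AT1G29090, annotated as a cysteine protease family gene, at -1.52 (SE 0.35). The GDSL lipase-like gene AT4G18970 followed at -1.45, the lipoxygenase gene LOX1 at -1.36, ABCI20 at -1.23 and the extensin gene EXT3 at -1.20. The protease gene RD21B and the methyltransferase gene HOL1 had log2 fold changes of -0.98 and -0.91. Adjusted p-values of these 8 genes in edgeR lay between 0.00248 and 0.0313. In the authors' deposited table AT4G18970 had -0.52, EXT3 -0.67, ABCI20 -0.70 and RD21B -0.78. There AT1G29090 had -1.66, LDA -1.17, LOX1 -1.15 and HOL1 -1.03.

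These counts depended on the tool and on single libraries. DESeq2 called 8 genes, all higher, whereas limma-voom called 31, with 24 higher and 7 lower, all among the 35 of edgeR. Without vil1-1 replicate 2 edgeR called 19, of which 15 were higher and 4 lower. Of the 20 called genes named above, LEA4-5, AT1G04560, EXPA2, ICL, RD21B and LDA kept their calls with each library left out in turn, and the other 14 lost it without at least 1 library. FBA6 was not called in any of the 5 such settings in which it was tested (edgeR adjusted p = 0.0626 to 0.21), with log2 fold changes from 1.38 to 2.32, the latter without Col-0 replicate 2. AT5G20950 was not called in the 3 in which it was tested (edgeR adjusted p = 0.186 to 0.26), though its log2 fold change stayed at 1.53 to 1.65. LOX1 went to -1.99 without vil1-1 replicate 2.

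Of the regulators of seed maturation and the genes of the hormone abscisic acid (ABA), only 3 had enough counts to be tested singly, and none was called: COR47 (-0.09, edgeR adjusted p = 0.941), PYL4 (-0.14, edgeR adjusted p = 0.83) and HAB1 (-0.03, edgeR adjusted p = 0.984). Of 11 seed maturation regulators in the authors' deposited table, 3 were higher, the transcription factor genes ABI3 (2.29-fold), ABI4 (1.87-fold) and ABI5 (1.76-fold), and none was lower (list adjusted p = 0.00163, cameraPR). Of 9 ABA- and dehydration-responsive genes, 6 were higher in the authors' deposited table, led by RAB18 (1.58) and RD29B (1.41), with list adjusted p = 1.54e-14 in cameraPR and 0.000243 on ranks. In the ABA signalling core, 5 of 25 genes were higher and 2 lower in the authors' deposited table, or 10 called adjusted over the list alone, and the list was not called (adjusted p = 0.292, cameraPR). The receptor gene PYL2 was 2.14-fold higher in the authors' deposited table. Phosphatase genes called in the authors' deposited table went both ways, with AHG1 (8.16-fold), HAI3 (2.96-fold) and PP2CA (1.55-fold) higher and ABI1 (1.78-fold) lower. None of 13 ABA metabolism genes passed in the authors' deposited table (list adjusted p = 0.682, cameraPR). The summed counts of these 4 lists were not called (edgeR adjusted p = 0.16, 0.289, 0.289 and 0.289). That of ABA metabolism was -0.70 and was called lower without Col-0 replicate 3 (-1.18, edgeR adjusted p = 0.0266), with -0.32 without Col-0 replicate 2, -0.28 without vil1-1 replicate 3 and -1.24 without vil1-1 replicate 2.

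Gibberellin genes were called as a list in the authors' deposited table (adjusted p = 0.00065, cameraPR), with 5 of 23 higher, 7 adjusted over the list alone. They hold both the DELLA repressor genes RGL2 (0.97) and RGL3 (1.02) and the biosynthesis genes GA20OX3 (1.74) and GA20OX2 (1.46), in the authors' deposited table. Summed counts of the gibberellin list were not called (log2 fold change 0.08, SE 0.12, edgeR adjusted p = 0.596). GA3OX2 made up most of this sum, with 5879.5 of 6102 CPM in Col-0 and 5986.9 of 6245.9 CPM in vil1-1. The sum therefore says little about the other members. This share describes the count files: in the authors' deposited table GA3OX2 had a mean log2 CPM of 7.99, a much lower level.

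Root hair markers were lower in vil1-1 in the authors' deposited table, 4 of 7 or 6 adjusted over the list alone, with a median of -1.08 (adjusted p = 0.000288, cameraPR). EXPA18 (-1.79), LRX1 (-1.32), COBL9 (-1.27) and PRP3 (-1.08) were the 4 called. Of 21 cell cycle and DNA replication genes, 6 were lower in the authors' deposited table, among them PCNA2 (-0.54) and MCM6 (-0.57), with list adjusted p = 0.00204 in cameraPR. In the count files the root hair list held 7 counts in Col-0 and 3 in vil1-1, too few for a test, and the cell cycle list was not called (log2 fold change -0.30, SE 0.23, edgeR adjusted p = 0.35). The cell cycle median in the authors' deposited table was of similar size, at -0.28, so the counts do not show a lack of difference.

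Photosynthesis genes were not called as a list in the main setting, with log2 fold change -0.07 (SE 0.10, edgeR adjusted p = 0.594) for summed counts and 1 of 41 higher and 2 lower in the authors' deposited table, 4 adjusted over the list alone. Camera gave adjusted p = 0.384 for them on the counts, and adjusted p = 0.562 with an estimated correlation. It called them lower with no filter (median -0.24, adjusted p = 0.0213), with CPM above 1 (-0.27, adjusted p = 0.0321) and without Col-0 replicates 2 and 3 together (-0.42, adjusted p = 0.0202). Ribosomal protein genes had camera adjusted p = 0.288 and adjusted p = 0.466 with an estimated correlation, and a log2 fold change of 0.06 (SE 0.07, edgeR adjusted p = 0.536) in summed counts. Of 281 such genes, 12 were higher and 1 lower in the authors' deposited table, 9 adjusted over the list alone, with a median of 0.06 (adjusted p = 0.000868, cameraPR).

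Polycomb and H3K27 demethylase genes showed no call among 21 in the authors' deposited table (list adjusted p = 0.883, cameraPR), where CLF had 0.23, SWN 0.33, EMF2 -0.21 and VRN2 -0.43. FLC, the floral repressor, had -0.07 (adjusted p = 0.869) in the authors' deposited table, and of 11 flowering regulators MAF5 (0.88) was the 1 called (list adjusted p = 0.883, cameraPR). Of 16 floral homeotic and KNOX genes, PI (-1.41) was the 1 called in the authors' deposited table (list adjusted p = 0.167, cameraPR). Seed coat markers had 0 of 11 called and endosperm markers 0 of 4, or 1 adjusted over the list alone, in the authors' deposited table (list adjusted p = 0.682 and 0.854, cameraPR).

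**Figure D2:**
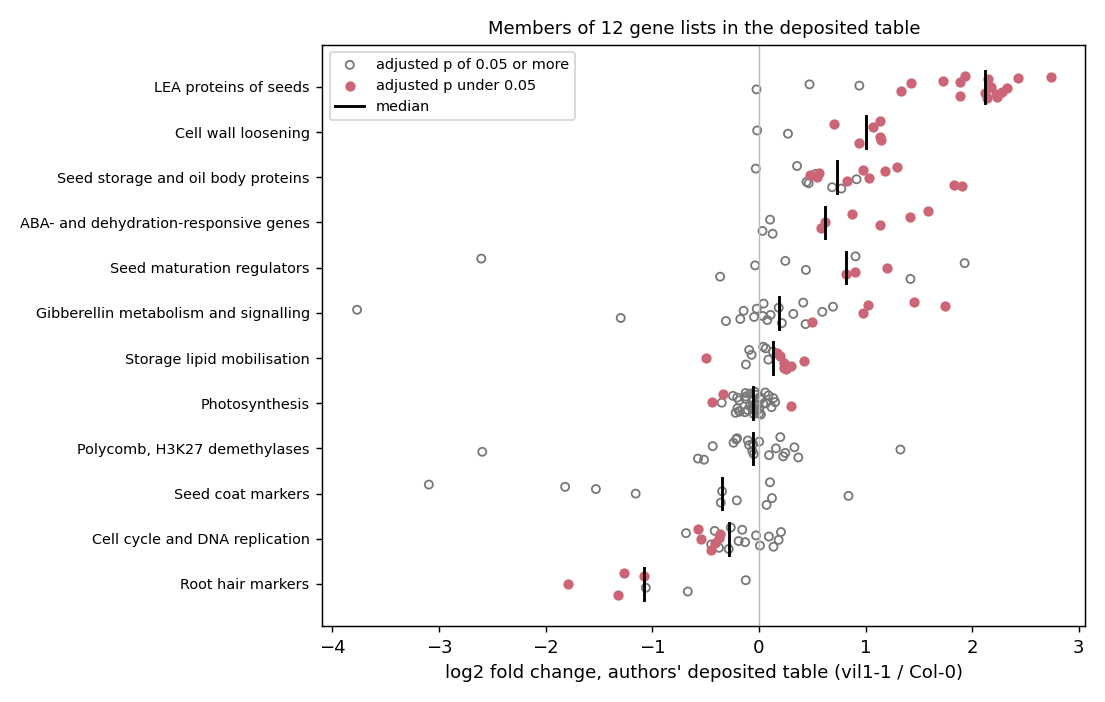
Log2 fold changes of vil1-1 over Col-0 in the authors' deposited table for the members of 12 gene lists, 1 circle per gene, filled where the adjusted p was under 0.05, with black bars at the medians. The LEA median lies at 2.12 and the root hair median at -1.08.

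Over all genes of the authors' deposited table, 1784 passed the adjusted p of 0.05, with 889 higher and 895 lower in vil1-1. Of the 35 genes called from the counts, 33 were called in the authors' deposited table too, all 33 in the same direction, where 6.91 would be shared by chance. AT1G13570 and AT5G08200 were the exceptions. Across the 942 tested genes log2 fold changes from the counts and from the authors' deposited table had Pearson's r = 0.76 and Spearman's rho = 0.643, over genes that are not independent replicates. Both sources describe the same study, so the overlap is no independent evidence.

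**Figure D3:**
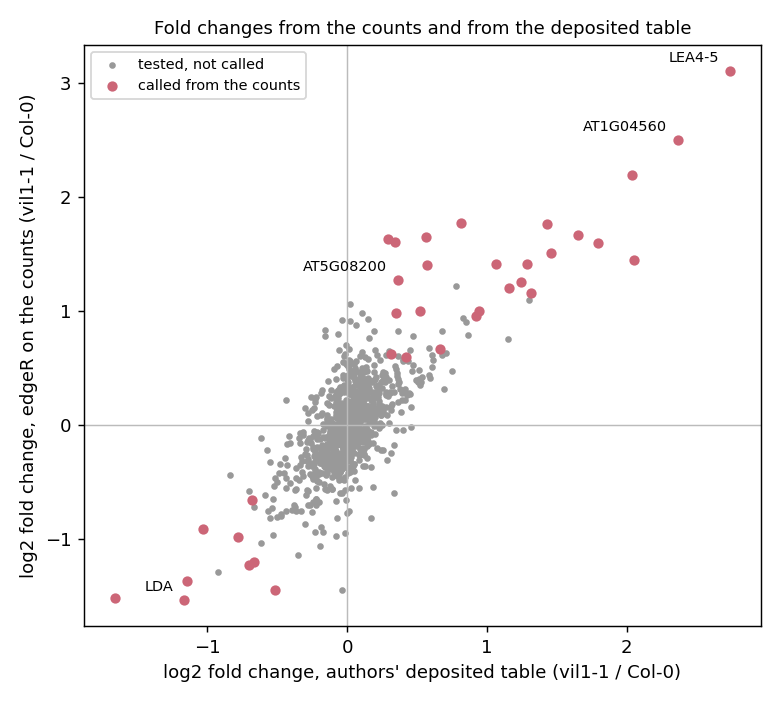
Log2 fold change of vil1-1 over Col-0 for 942 genes, from edgeR on the counts (vertical) against the authors' deposited table (horizontal), with the 35 called genes in red. LEA4-5 lies at 3.10 and 2.74 and LDA at -1.53 and -1.17.

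Libraries also differed in counts at near-silent genes, the 4834 with a mean log2 CPM under 0 in the authors' deposited table. These took 3.68, 9.77 and 7.59 of every 10000 counts in Col-0 replicates 1, 2 and 3, and 2.77, 4.46 and 3.00 in the vil1-1 libraries. Without Col-0 replicates 2 and 3 together, a check chosen after seeing the data that leaves 1 Col-0 library and takes it to vary like vil1-1, edgeR called 7 genes, 6 higher and 1 lower. The LEA rise was then 2.01 (edgeR adjusted p = 2.1e-06), whereas storage and oil body genes (0.74, edgeR adjusted p = 0.234), cell wall loosening (0.46, edgeR adjusted p = 0.211) and storage lipid mobilisation (0.35, edgeR adjusted p = 0.0794) were no longer called.

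**Figure D4:**
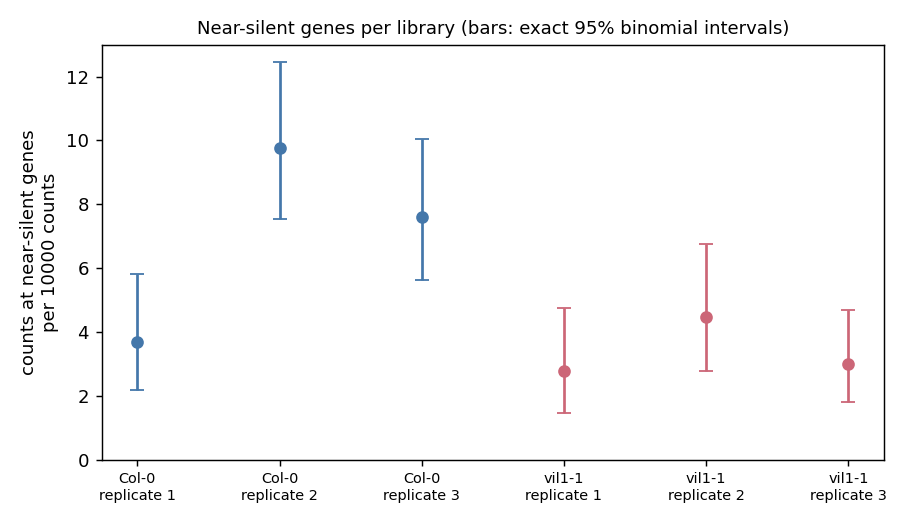
Counts at 4834 near-silent genes per 10000 counts in each of the 6 libraries, with exact 95% binomial intervals (Clopper-Pearson). Col-0 replicates 2 and 3 lie at 9.77 and 7.59 and the other libraries between 2.77 and 4.46.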

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

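Leaving out Col-0 replicates 2 and 3 together or ribosomal RNA loci, summing lists, leaving out the member with the largest rise, and list tests on the authors' deposited table were chosen after seeing the data. The 35 calls (26 higher, 9 lower) were the same genes with RLE, the replicate block, and without organelle loci, which held no counts. Same-numbered libraries had deviation correlations of 0.079, -0.033 and 0.019, within the range of differently numbered pairs across genotypes (-0.11 to 0.104). At this depth a small effect of a shared day or batch cannot be told apart from none. The block (35 calls) changed no call named here. Calls numbered 8 with DESeq2 (8 higher, 0 lower, 55 genes at an unadjusted p under 0.05), 21 with no filter (16 and 5, 17 shared), 22 at an adjusted p under 0.01 (4 lower) and 7 without Col-0 replicates 2 and 3 (6 and 1). The filter on CPM above 1, meant as stricter, was looser at this depth, with 8801 genes tested and 32 called. Leaving out 1 library gave 19 to 36 calls, 15 to 22 higher and 4 to 15 lower, with 15 lower without vil1-1 replicate 1, 19 calls (15 and 4) without vil1-1 replicate 2 and 5 lower without vil1-1 replicate 3. The real split called 35 genes, the highest of the 9 others 0, and 1 of 10 splits was as large, but 10 splits are too few for a share under 0.05. Calls shared with the authors' deposited table numbered 8 for DESeq2 and 16 at an absolute log2 fold change of at least 1, where 25 of the tested genes were called from the counts and 19 in the authors' deposited table (568 over all its genes). Fewer genes or libraries enter some of these settings, and otherwise the cause was not tested.

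The LEA sum stayed called in every setting run (log2 fold change 1.84 to 2.27 with 1 library left out). Without Col-0 replicates 2 and 3, the calls of storage and oil body (0.74), cell wall loosening (0.46) and lipid mobilisation (0.35) were lost, and that of lipid mobilisation also with no filter (0.27), with CPM above 1 (0.29) and without ICL (0.047). Without 1 library the ABA metabolism sum ran from -1.24 to -0.28 and was called without Col-0 replicate 3 (-1.18). Uncalled sums changed sign: Polycomb with limma-voom (0.051), thinning (0.038) and 1 library left out (-0.19 to 0.25), gibberellin (-0.082 without Col-0 replicates 2 and 3, -0.063 to 0.17 without 1 library), light signalling (-0.004 with library totals, -0.012 with no filter, -0.021 thinned, -0.025 to 0.18 without 1 library), flavonoid (0.079 without Col-0 replicates 2 and 3) and ribosomal (-0.001 with no filter). Without 1 library photosynthesis ran from -0.13 to 0.018 and auxin from -0.67 to 0.053. Camera's cell wall call (median 0.76) was lost with an estimated correlation. It called photosynthesis lower with no filter (-0.24), CPM above 1 (-0.27) and without Col-0 replicates 2 and 3 (-0.42), and its median ran from -0.26 to 0.01 without 1 library. In the authors' deposited table the Polycomb median was -0.051 at a log2 CPM of at least 1. On ranks, flowering (-0.11) changed direction and flavonoid (-0.24) and auxin (-0.15) lost their calls.

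The 22 called genes named in the text never changed sign. Uncalled members of the lists did, near 0. With 1 library left out, PYL4 ran from -0.33 to 0.008, HAB1 from -0.13 to 0.03, COR47 from -0.35 to 0.078, GA3OX2 from -0.13 to 0.16, PHYA from -0.17 to 0.38, PSAF from -0.23 to 0.036, ELF4 from -0.08 to 0.95, and the ribosomal genes AT5G56710 from -0.15 to 0.008 and emb2171 from -0.14 to 0.10. GA3OX2 had -0.016 with CPM above 1 and -0.136 without Col-0 replicates 2 and 3, and PSAF 0.044 thinned. The gene emb2171 had -0.018 with library totals, -0.021 with no filter, -0.047 with CPM above 1, -0.008 thinned and -0.032 without Col-0 replicates 2 and 3.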

Other observations

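Flavonoid genes leaned lower in vil1-1: 4 of 11 were lower in the authors' deposited table, 6 adjusted over the list alone, with CHI at -0.68, FLS1 at -0.59, LDOX at -1.28 and CHS at -0.24 (list adjusted p = 0.0161 in cameraPR, and 0.205 on ranks). Of 16 auxin genes, 3 were lower in the authors' deposited table, GH3.3 (-2.42), IAA7 (-1.12) and IAA4 (-0.49), with list adjusted p = 0.00279 in cameraPR and 0.153 on ranks. In the light signalling list PIF3 (-0.66) was lower and PHYA (0.38) and PAR2 (0.59) higher in the authors' deposited table, 4 called adjusted over the list alone, and the list was not called (adjusted p = 0.682, cameraPR). BOA (0.79) was the 1 called of 19 clock genes in the authors' deposited table (list adjusted p = 0.337, cameraPR). None of 14 heat shock and 8 defence genes was called in the authors' deposited table (list adjusted p = 0.695 and 0.925, cameraPR). Summed counts of the flavonoid, auxin, light signalling and clock lists were not called (edgeR adjusted p = 0.536, 0.57, 0.922 and 0.16).

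QQS, an orphan gene tied to starch, had the largest log2 fold change among called genes of at least 5 CPM in the authors' deposited table, at 5.51, followed by the sucrose synthase gene SUS1 at 2.77. CBR (-4.10) and AT4G06477 (-4.28) were the lowest of these genes in the authors' deposited table. AT4G06477 had 0, 15 and 4 counts in Col-0 and 0 in each vil1-1 library, and CBR had 3, 6 and 1 in Col-0 and 0 in each vil1-1 library.

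Tests of the seed programme below were all chosen after the result was seen, as were those of levels between the 2 sources, except that of shared sequence. Whether the vil1-1 libraries held more endosperm cannot be decided from 1 marker. EPR1, the 1 endosperm marker above 10 CPM, did not rise with the LEA genes. It had 0.14 in the authors' deposited table (95% interval -0.02 to 0.29) beside the LEA median of 2.12. The 3 seed coat markers above 10 CPM averaged -0.01 there (95% interval -0.19 to 0.17). This interval takes the errors of the 3 genes as independent, so it may be too narrow. Seedlings may express these markers, so a small share of seed coat cannot be told apart from none. An earlier stage of vil1-1 seedlings is consistent with the lower root hair markers in the authors' deposited table (median -1.08). In green tissue an earlier stage cannot be told apart from the same stage. The photosynthesis median of -0.06 (95% bootstrap interval -0.10 to -0.02) in the authors' deposited table covers members that go both ways (-0.44 to 0.31). That interval resamples genes and does not measure variation between seedling samples. Camera on the counts called the photosynthesis list lower with no filter (-0.24) and with CPM above 1 (-0.27). The median was -0.42 without Col-0 replicates 2 and 3. A later sowing, slower germination and an effect of the genotype on seed genes all stay open, since the labels do not separate them.

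Levels in the count files also differed from those in the authors' deposited table. After scaling to the median, 69.4% of the 490 genes above 300 CPM in the authors' deposited table lay outside the 99% Poisson range of their expected count, which argues against the count files as a random sample of the same gene counts. AT3G03270, called from the counts, had 6149 counts, 35.1 times its expected number, and the snoRNA gene AT2G35382 had 1 count, 0.00974 times. Overlap with a gene on the other strand shifted the median log2 ratio by 0.07 (95% bootstrap interval -0.01 to 0.15, 862 of 3270 genes above 50 CPM). That argues against a common shift of overlapping genes. Their spread was not compared, so gains and losses that cancel stay open. Shared 31-mers had a Spearman's rho of -0.03 with the size of the deviation (-0.06 to 0.01, across genes), which argues against shared sequence. A different counting step or library selection stays open, and no biological explanation was tested.

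Of the tests of near-silent genes, those of depth and of genotype were chosen after the result was seen, and that of gene length before. Among the 1973 genes of the authors' deposited table with a mean log2 CPM under -0.5, 77.9% were lower in vil1-1 (1537 genes, exact 95% binomial interval 76.0 to 79.7%). None was called there, and none was among the 942 genes tested in the counts, but these genes enter the adjustment and the list tests of the authors' deposited table. Limited to genes with a mean log2 CPM of at least 1, all 12 lists called in the authors' deposited table were called in the same direction. In the count files Col-0 libraries held 71.0% of the 186 counts at near-silent genes (exact 95% interval 63.9 to 77.4%) but 53.0% of all counts. Depth of the count files falls short of this share, although the interval takes counts as independent. The excess lay in Col-0 replicates 2 and 3 (9.77 and 7.59 per 10000), with replicate 1 (3.68) within the vil1-1 range (2.77 to 4.46). Depth behind the authors' deposited table is not given, so its part in the lean there cannot be judged. In the count files the genotypes had 7.01 ± 3.08 and 3.41 ± 0.92 counts at near-silent genes per 10000 (SD, n = 3 each). A two-sided exact permutation test gave p = 0.20, where 3 against 3 cannot go below 0.10, so a genotype effect stays open. Reads scattered over the genome may contribute, since the protein-coding genes lower in vil1-1 were longer than genes absent from the authors' deposited table (area under the curve 0.641, 95% bootstrap interval 0.622 to 0.660). Genes higher in vil1-1 had an area of 0.606 (0.576 to 0.637) and real transcripts of long genes also yield more reads, so length does not separate these explanations. The 2 sides did differ in pseudogenes, which the length test left out. Pseudogenes made up 36.8% of the 1537 genes lower in vil1-1 and 14.9% of the 436 higher, a contrast whose cause was not tested.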
